A study of Setaria viridis with 9 samples.

How the data were processed

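Leaf polyadenylated RNA of Setaria viridis was sequenced as paired-end reads from a stranded library kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, StringTie 2.2.3, edgeR 4.4.1 and limma 3.62.2. The aligner and the genome build are not given in the sources used here, so no coordinates are printed. The authors deposited 1 table for the whole series with 17987 genes. Per the file headers it holds whole-number counts per gene and library, which were used without change for every test here. It also holds corrected log2 CPM per library and the authors' log2 fold changes, per the file headers, but no header says what was corrected. The deposited t and B statistics were treated as a score, and the deposited p-values and adjusted p-values were read as the authors' own results for ndhO and pgr5 against WT. The WT count columns carry the library names given in the labels. The ndhO and pgr5 columns carry an extra number between the name and the replicate number, whose meaning is not given in the sources used here, and were matched to samples by group and last number. Replicates were those the labels call biological.

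Gene names and descriptions came from the deposited table. RefSeq identifiers of the assembly GCF_005286985.2 matched 17558 of the 17987 genes and were used only for symbols and for which genes neighbour each other. Of the genes, 4002 carry a description that calls them uncharacterized. Reads shared between near-identical gene copies could have been split by the authors' counting, so single members of families such as ribosomal proteins are uncertain.

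Totals were 18407334, 13641341 and 11606570 counts in the libraries labelled WT 1, 2 and 3. They were 14015773, 18171722 and 14209173 counts in those labelled ndhO 1, 2 and 3, and 18837265, 12334320 and 17089682 counts in those labelled pgr5 1, 2 and 3. The common biological coefficient of variation was 0.383. Spearman correlations between libraries across genes ran from 0.939 to 0.977 within a label (median 0.952) and from 0.921 to 0.976 between labels (median 0.958).

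Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the default filter on low counts, which kept 17970 genes, and quasi-likelihood tests with robust dispersions in 1 fit over all 9 libraries with genotype as the only term. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Fold changes are log2 with standard errors from the F statistic. Means are CPM on TMM-scaled library sizes. The 3 contrasts were ndhO against WT, pgr5 against WT and pgr5 against ndhO. With 3 against 3 libraries an exact permutation test cannot give a p below 0.1, so none was used. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated correlation, adjusted over 84 tests. Of 29 lists defined by words in the descriptions, 28 had at least 3 tested genes. The list of organelle-encoded transcripts did not and was not tested. No annotation terms were given, so no enrichment of terms was run.

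Named genes followed a rule: the edited genes, the largest changes past the threshold in each contrast, the lowest adjusted p of each list or, where none passed, its most abundant member, and genes called in both contrasts against WT. No gene passed the threshold, which left the edited genes and the most abundant member of each list. Genes named outside the rule are said to be chosen after their values were seen. The design, the lists, the rule and most alternatives were fixed before the data were examined. Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, fits of 2 genotypes only, a replicate block and leaving out each library. The alternative of a pseudocount for normalized values did not apply, since counts were deposited.

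The procedure was tested on simulated data for pgr5 against WT, drawn from the real means, library sizes and dispersions of 17970 genes, with changed genes taken from those with a mean of at least 50 counts. It recovered 13% of 100 genes changed 2-fold and 82% of 100 changed 4-fold, and called 6 of 17770 unchanged genes. A list of 183 genes moved by 0.5 on the log2 scale was called (adjusted p = 2.04e-23) and 0 of the other 27 lists were. The simulated genes were independent, so that result says nothing about lists whose genes vary together. The camera test with an estimated correlation was not tried on simulated data, so its power is not known.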

Results

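Polyadenylated RNA was sequenced from whole-leaf tissue of Setaria viridis, a small grass that fixes carbon by the C4 pathway and serves as a laboratory model for maize and sorghum. The labels divided 9 libraries into 3 genotypes with 3 biological replicates each: wild type (WT), gene-edited plants with null NdhO alleles, and gene-edited plants with null PGR5 alleles. NdhO is a subunit of the chloroplast NADH dehydrogenase-like (NDH) complex, and PGR5 is a small thylakoid protein, and both belong to routes of cyclic electron flow around photosystem I. The design asked how loss of each route altered the leaf transcriptome relative to WT. The deposited table held counts for 17987 genes, with totals from 11606570 to 18837265 counts per library. Because the transcripts of the edited genes did not follow the genotype labels, every group below is a set of libraries labelled with a genotype, and every direction is a direction between labels.

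The edited genes came first, as a check of those labels. NdhO (LOC117858157, SEVIR_5G467100v2) stood at 245, 443 and 446 CPM, counts scaled to library size, in the libraries labelled ndhO 1, 2 and 3. In the libraries labelled WT 1, 2 and 3 it stood at 44.3, 617 and 230.0 CPM, and in those labelled pgr5 1, 2 and 3 at 421, 20.5 and 48.4 CPM. The lowest NdhO levels were therefore in the libraries labelled pgr5 2, WT 1 and pgr5 3, and none was in a library labelled ndhO. PGR5 (LOC117861247, SEVIR_6G259600v2) stood at 287, 250 and 389 CPM in the libraries labelled pgr5 1, 2 and 3. It stood at 376, 46.5 and 42.8 CPM in those labelled WT 1, 2 and 3, and at 38.1, 318 and 338 CPM in those labelled ndhO 1, 2 and 3. The lowest PGR5 levels were in the libraries labelled ndhO 1, WT 3 and WT 2. A null allele need not lower its transcript, so a high level in a library labelled for that allele does not by itself contradict the label, but the spread within the WT label was 13.9-fold for NdhO and 8.79-fold for PGR5.

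**Figure D1:**
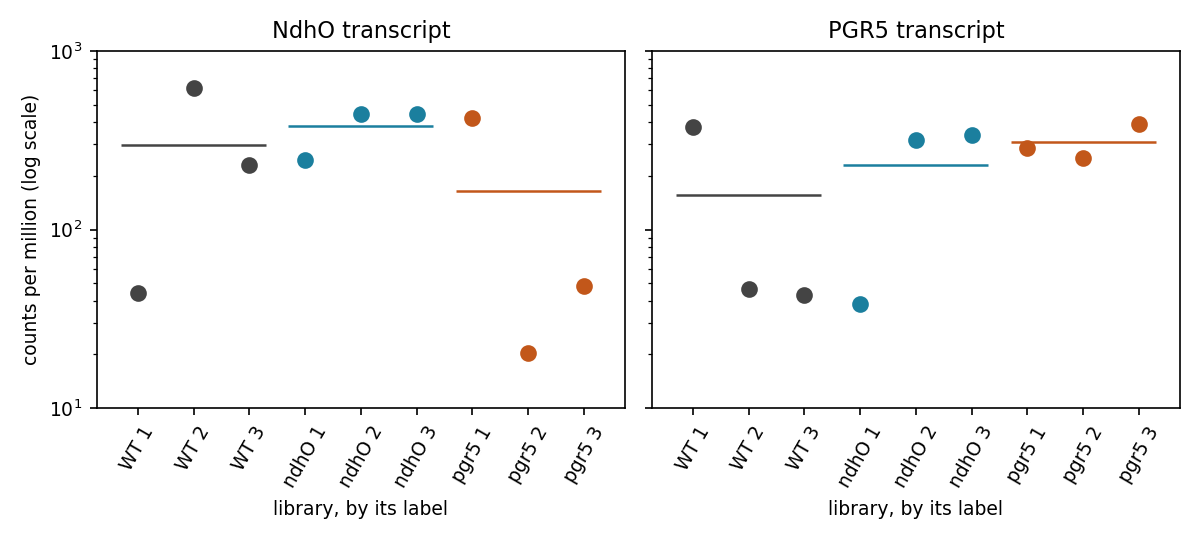
CPM (log axis) of the NdhO and PGR5 transcripts in each of the 9 libraries, placed and coloured by the genotype label, with 1 point per library and a line at each label's mean. NdhO was lowest in the library labelled pgr5 2 (20.5 CPM) and PGR5 in the library labelled ndhO 1 (38.1 CPM).

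By label, mean NdhO was 378 ± 115 CPM (SD, n = 3) for ndhO and 297 ± 292 CPM (SD, n = 3) for WT, a log2 difference of 0.35 with a standard error of 1.17 and an edgeR adjusted p of 1.00. Mean PGR5 was 308 ± 72.0 CPM (SD, n = 3) for pgr5 and 155 ± 191 CPM (SD, n = 3) for WT, a log2 difference of 0.99 with a standard error of 1.00 and an edgeR adjusted p of 1.00. The NdhO difference was smaller than either label's SD, and the PGR5 difference was smaller than the SD of the WT label and larger than that of the pgr5 label. Among the 22 genes of the NDH list, the highest and lowest library differed 30.1-fold for NdhO, 11.6-fold for the CRR1 gene LOC117840609, which was named after its values were seen, and less than that for each of the others.

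In the comparison of libraries labelled ndhO with those labelled WT, no gene of the photosynthetic lists passed edgeR's test. The 22 NDH genes had a median log2 fold change of -0.06. The most abundant of them, subunit B5 of the NDH complex (LOC117856781), stood at 748 ± 43.6 CPM against 771 ± 255 CPM in WT (SD, n = 3). The photosystem I list had 0 of 10 genes past the threshold and a median of -0.15, and the photosystem II list 0 of 17 and a median of 0.08. Chlorophyll a-b binding protein 1 (LOC117844591), an antenna protein, stood at 9760 ± 1738 against 10455 ± 2573 CPM (SD, n = 3). Pyruvate, phosphate dikinase 2 (LOC117850669), which regenerates the CO2 acceptor of the C4 cycle, stood at 41430 ± 6177 against 39672 ± 8217 CPM (SD, n = 3), and 0 of the 48 C4 genes tested passed. Across 17970 genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p of 0.05, with 493 at an unadjusted p under 0.05, and 869 without WT 2. Uniform p-values would give 898.5, which other splits of these libraries, given below, need not reach. DESeq2 called 7 higher and 9 lower, and limma-voom 0. Without the library labelled WT 3, the camera test at its preset correlation called 4 photosynthetic lists lower, namely the NDH complex (adjusted p = 0.00472), photosystem I (7.03e-04), the antenna (0.00266) and the Calvin-Benson cycle (0.0150). With an estimated correlation, 0 lists were called there or with any other library left out (lowest adjusted p = 0.957), and with all 9 libraries that correlation was 0.82 for photosystem I, 0.78 for the antenna, 0.51 for the NDH list and 0.39 for the Calvin-Benson list. Relative to each gene's mean, these lists had medians from -0.60 to -0.44 in the library labelled WT 3. Their medians were also low in ndhO 1 (-0.45 to -0.24) and pgr5 2 (-0.47 to -0.16). Each label thus held a library low in these lists, and leaving out WT 3 removed that of WT alone. Without ndhO 1 the camera test called photosystem II (adjusted p = 0.0224) and photoprotection (0.0313) higher, again only at the preset correlation. In 8.63% of genes the 3 libraries of each label did not overlap, where chance gives 10%.

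In the comparison of libraries labelled pgr5 with those labelled WT, the same photosynthetic lists held no called gene. PGR5-like protein 1A (LOC117840897), the partner of PGR5 in the thylakoid, stood at 1893 ± 144 against 1722 ± 259 CPM (SD, n = 3). FTSH 2 (LOC117852324), a protease of photosystem II repair, stood at 1719 ± 181 against 1521 ± 367 CPM (SD, n = 3), and 0 of the 30 photoprotection genes passed. Glyceraldehyde-3-phosphate dehydrogenase B (LOC117837837) of the Calvin-Benson cycle stood at 7779 ± 1588 against 7459 ± 1377 CPM (SD, n = 3), with 0 of 35 genes of that list past the threshold. Catalase isozyme C (LOC117840633), which removes hydrogen peroxide, stood at 1599 ± 149 against 1709 ± 355 CPM (SD, n = 3), with 0 of 44 scavenging genes past it. edgeR's test called 0 genes higher and 0 lower, with 371 at an unadjusted p under 0.05, which became 644 without WT 1, 583 without WT 2 and 612 without pgr5 1. DESeq2 called 3 higher and 3 lower, and limma-voom 0. Without the library labelled WT 3, camera called the NDH complex (adjusted p = 0.00201), photosystem I (4.69e-04) and the antenna (2.36e-04) lower, and without WT 2 it called the Calvin-Benson cycle higher (0.0458), all at the preset correlation and none with an estimated one (lowest adjusted p = 0.957). WT 3 and pgr5 2 were both low in the 3 lists called without WT 3, so leaving it out left only the pgr5 label with a low library. The libraries of the pair of labels did not overlap in 6.32% of genes, where chance gives 10%. In counts simulated for this comparison, with 100 genes changed 2-fold and 100 changed 4-fold among 17970, the test recovered 13 of the former and 82 of the latter. Most simulated 2-fold changes were thus missed at the dispersions fitted under these labels. Those dispersions depend on the labels, with a common biological coefficient of variation of 0.383 as deposited and 0.337 with the labels moved by 1 column. The recovery may therefore not hold for the real genes.

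Libraries labelled pgr5 were also compared directly with those labelled ndhO. Lipoxygenase 2.3 (LOC117844140), which starts jasmonate synthesis, stood at 2441 ± 440 against 3335 ± 254 CPM (SD, n = 3), a log2 difference of -0.45 with a standard error of 0.25 and an edgeR adjusted p of 1.00. The jasmonate list as a whole had a median of 0.44 in this contrast, and 0 of its 27 genes passed. The sucrose transporter SWEET13-like (LOC117850592) stood at 1619 ± 265 against 1307 ± 93.0 CPM (SD, n = 3). edgeR's test called 0 genes higher and 0 lower, with 480 at an unadjusted p under 0.05 (839 without pgr5 1), while DESeq2 called 9 higher and 3 lower and limma-voom 0. Without the library labelled ndhO 1, camera called photosystem II (adjusted p = 0.0313), photoprotection (0.0220) and the C4 cycle (0.0313) lower at the preset correlation. It called none of them with an estimated one, where its lowest adjusted p over all contrasts and left-out libraries was 0.957. The libraries did not overlap in 8.25% of genes, where chance gives 10%. A test for any difference among the 3 labels also called 0 genes, with 343 at an unadjusted p under 0.05.

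Among 28 gene lists fixed before the data were examined, the cytosolic ribosomal proteins, the protein components of the ribosomes of the cytosol, were the single list called by the camera test with a preset correlation of 0.01. Their median log2 fold change was 0.45 for pgr5 against WT (adjusted p = 1.58e-17), 0.29 for pgr5 against ndhO (adjusted p = 2.30e-04) and 0.17 for ndhO against WT (adjusted p = 7.19e-04). With an estimated correlation the adjusted p was 0.990 in every contrast. The power of that version was not tested, so its lack of calls here and for other lists does not show that a list was unchanged. Fitted values lay above 0 for 180, 168 and 163 of the 183 genes in these contrasts, and 0 genes passed edgeR's test over all genes. Adjusted over the list alone, 1 gene passed for ndhO against WT (LOC117833632, a 60S ribosomal protein L10-like gene chosen after its values were seen, adjusted p = 0.0306) and 0 in the other contrasts, and DESeq2 called that gene over all genes for ndhO (adjusted p = 6.37e-05) and pgr5 (adjusted p = 0.0255) against WT. The list's median, relative to each gene's mean, was 0.94 in the library labelled pgr5 3 and between -0.54 and 0.30 in the other 8. Without that library the adjusted p was 0.563 for pgr5 against WT, and the direction turned for pgr5 against ndhO, with an adjusted p of 5.05e-04. The call for ndhO against WT ended without WT 3 (adjusted p = 0.625) or ndhO 2 (adjusted p = 0.687), and that for pgr5 against ndhO ended without ndhO 1 (adjusted p = 0.215).

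**Figure D2:**
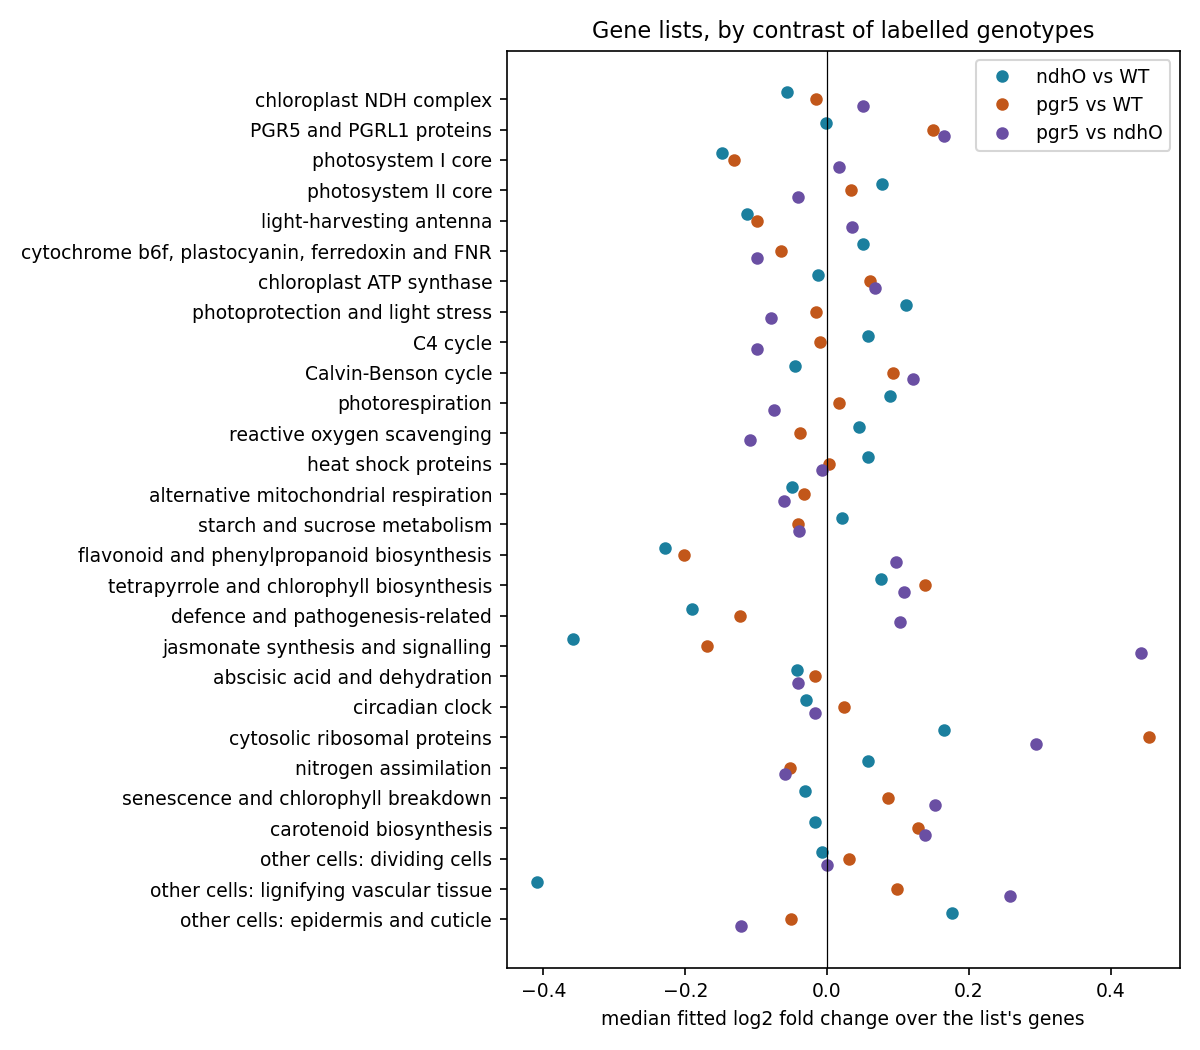
Median fitted log2 fold change over the genes of each of 28 lists, with 1 point for each contrast between labelled genotypes and a line at 0. The cytosolic ribosomal proteins reached 0.45 for pgr5 against WT, a value that rested on the library labelled pgr5 3.

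No other list was called in any contrast with all 9 libraries, and the calls below with a library left out held only at the preset correlation (lowest adjusted p = 0.957 with an estimated one). For ndhO against WT, jasmonate genes had a median of -0.36 (camera adjusted p = 0.217), flavonoid and phenylpropanoid genes -0.23 and defence genes -0.19. The jasmonate list was called lower there without WT 2 (adjusted p = 0.0458) or WT 3 (0.0164), and in pgr5 against WT without pgr5 3 (0.00762). In pgr5 against WT the flavonoid list was called lower without WT 3 (adjusted p = 0.00700) or pgr5 1 (0.0136), and tetrapyrrole genes higher without WT 2 (0.0458) or pgr5 2 (0.0395). Scavenging genes had a median of -0.11 in pgr5 against ndhO, with 29 of 44 below 0 (camera adjusted p = 0.0785), and were called lower there without ndhO 1 (0.0220) or pgr5 1 (0.00387) and higher in ndhO against WT without WT 2 (0.0369). Among markers of other cells, dividing cells had medians of -0.01 for ndhO and 0.03 for pgr5 against WT, lignifying vascular tissue -0.41 and 0.10, and epidermis and cuticle 0.18 and -0.05. In pgr5 against ndhO the epidermis and cuticle genes had a median of -0.12, with 61 of 88 below 0 (camera adjusted p = 0.0785, and 0.990 with an estimated correlation). They were called lower there without ndhO 1 (adjusted p = 0.0313), ndhO 2 (0.0494) or pgr5 1 (0.0175). For lignifying vascular tissue in pgr5 against WT the median of 0.10 and the mean of -0.11 differed in sign, and the camera test pointed down, with a call without WT 3 (adjusted p = 0.0316) or pgr5 3 (0.00762). The remaining lists, from heat shock proteins and the circadian clock to starch, nitrogen, carotenoid, tetrapyrrole, photorespiration, abscisic acid and senescence genes, had 0 called genes, also when adjusted over each list alone.

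Both contrasts against WT shared their controls. Their fold changes correlated at 0.44 across 17970 genes, which are not independent replicates, and unchanged groups simulated against the same controls gave 0.50 (range 0.47 to 0.53 over 20 simulations). The covariance was 0.196 against a simulated 0.201. Without WT 1, 2 and 3 in turn the correlation was 0.73, 0.63 and 0.57, where simulation with the same pair of controls gave 0.64, 0.63 and 0.63 (means of 10 simulations). The covariance was then 0.683, 0.428 and 0.330 against a simulated 0.403, 0.400 and 0.402. Without WT 1 the correlation and covariance lay above every simulation (highest 0.669 and 0.451). Without WT 3 they lay below every one (lowest 0.601 and 0.372). Without WT 2 the correlation lay within the simulated range and the covariance just above it (highest 0.425). With all 9 libraries the shared controls alone would give a covariance close to that seen, which lay within the simulated range (0.179 to 0.230), and the correlation lay below its range. The simulated genes were independent, while real genes vary together, so the simulated ranges are too narrow. A value inside or outside them is therefore no test of a shared response. With 3 WT libraries the controls could not be split into parts of at least 2. Values with a library left out may therefore also come in part from the shared controls.

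The authors' deposited table gave a different count for pgr5. It listed 451 genes with an adjusted p under 0.05 for pgr5 against WT, 310 higher and 141 lower, and 0 for ndhO against WT, where the lowest adjusted p was 0.606. In the authors' deposited table LOC117860852 (GTP-binding protein ERG), 1 of 5 genes tied at the lowest adjusted p and chosen after its values were seen, had a log2 fold change of 6.52 there, 0 counts in the library labelled ndhO 3 and at least 25 counts in each of the other 8. Of the 451 genes, 165 (36.6%) had 0 counts in the library labelled ndhO 3, against 668 (3.71%) of all genes. All 165 were among the 310 higher genes (53.2%), while the 141 lower ones had a median of 106 counts in ndhO 3, against 49 and 64 in ndhO 1 and 2. In the edgeR fit to the deposited counts, 41 of the 451 (9.09%, exact binomial 95% interval 6.60 to 12.1%) had an unadjusted p under 0.05.

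**Figure D3:**
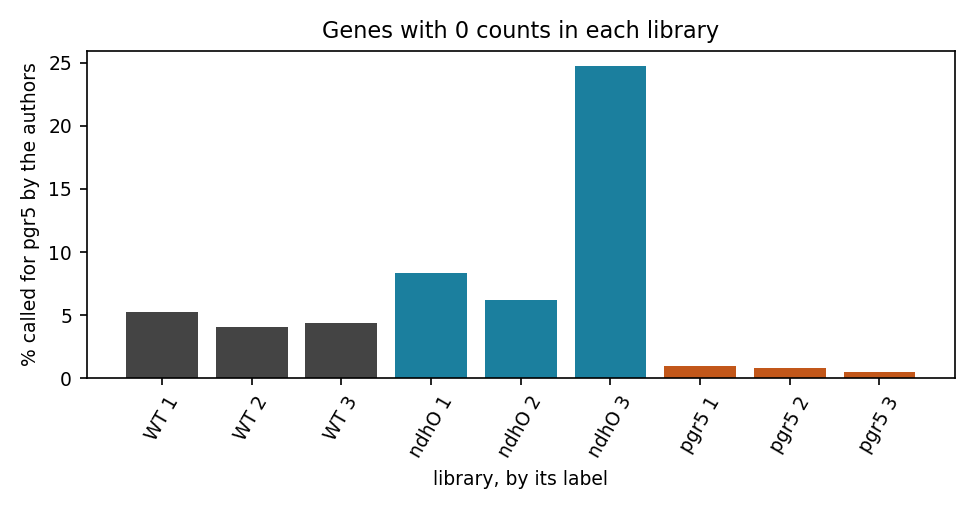
Percentage of the genes with 0 counts in each library that the authors' deposited table called for pgr5 against WT, with 1 bar per library coloured by its genotype label. The bar of the library labelled ndhO 3 reached 24.7% and the next highest, ndhO 1, 8.35%.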

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

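The tests of library labels moved along the columns, of the refit of the corrected values and of the genes at 0 in the library labelled ndhO 3 were chosen after the result was seen, and the other tests below before. Signals in columns outside the comparisons led to 2 of the results here: the 451 genes called for pgr5 in the authors' deposited table, and the corrected values of the library labelled ndhO 3, which equalled the mean of those of ndhO 1 and 2 in all 17987 genes (tolerance 1e-06). Groups of 3 are too small for a search for single outlying libraries.

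The authors' deposited table called 451 genes for pgr5 where the edgeR fit to the deposited counts called 0 (371 at an unadjusted p under 0.05), DESeq2 6 and limma-voom 0. The corrected values differ from the log2 counts by a shift of equal size and opposite sign in 5 and 4 libraries, with all WT-labelled libraries on one side and all pgr5-labelled ones on the other, so that the sides moved relative to each other by the gap between ndhO 3 and the mean of ndhO 1 and 2. limma on the corrected values, with voom weights from genotype alone, called the same 451 genes (largest log2 difference 4e-08), while the same shift kept as a term in the model called 0. The 451 calls were thus reproduced where the shift was removed before the test without its uncertainty. An earlier test, the share of the 451 genes at 0 in ndhO 3, gave 36.6% (interval 32.1 to 41.2%), between the bounds of 10 and 50% set for it. It held 165 of 310 higher genes (53.2%, interval 47.5 to 58.9%) and 0 of 141 lower ones. The share could not decide, since the shift raises pgr5 against WT for a gene at 0 in ndhO 3, so lower genes could hardly be counted. Of the lower genes 45 were at 0 in ndhO 1 or 2, against 7 of the higher ones. Across genes the shift followed the gap within the ndhO label with a correlation of 1 and a slope of 1. Whether some of the 451 genes differ in the counts themselves stays open by the test set for it. In edgeR 9.09% of the 451 genes had an unadjusted p under 0.05, and the interval, 6.60 to 12.1%, includes the bound of 10%. Of all 17970 genes 371 had such a p, and some excess is built in, since the authors' fold changes contain the uncorrected ones. Without the shift limma-voom called 0 genes, and its t statistics correlated with the authors' at 0.52. The 451 calls as a set thus depended on how the shift was handled, with 0 on the uncorrected counts and 0 with the shift as a term.

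The transcripts of the edited genes did not follow the genotype labels. Ordinary variation between wild-type plants is argued against, since both genes' folds within the WT label lay at or above the 99.8 percentile of 1000 genes of like abundance. Reads counted under a neighbouring tested gene are also argued against, since the sum of each gene with its neighbours still varied at least 6.55-fold. Reads counted under a gene outside those tested would not show. In the order of the columns the 3 lowest libraries were neighbours for each gene, counting the last column as next to the first, which holds for 36 of 1680 pairs of separate triples (0.0214 as a share). Labels moved by 1 column gave 62 genes with any difference, against 0 as deposited and 1 when moved by 2, and this was also the most among 100 drawn splits of the libraries, but splits unrelated to the columns reached 51 and 40, and up to 2564 genes at an unadjusted p under 0.05 against 1701 for the move. These values could come from sets of libraries moved along the columns. The genotype names moved by 1 would put the lowest PGR5 levels under WT and the lowest NdhO levels under pgr5. A larger move makes the same sets with the names in another order. In 1 such order the lowest NdhO levels fall under ndhO and the lowest PGR5 levels under pgr5. The libraries labelled ndhO 2, ndhO 3 and pgr5 1, high in both genes, then fall under WT. The test for any difference depends on the sets alone and cannot tell these orders apart. The move was looked for because of the edited genes, other mix-ups were not excluded, and no library was assigned another genotype.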

How the results depend on the processing

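The terms for the split of 5 and 4 libraries, the fit of pgr5 against WT without ndhO 3, and list tests with a left-out library and an estimated correlation, were chosen after seeing the data. The count of 0 genes in each direction and contrast held with both other scalings, both other filters, limma-voom, fits of 2 genotypes, a threshold of 0.01, each left-out library (range 0 to 0) and the split as a term in edgeR or limma-voom. DESeq2 differed, with 7 higher and 9 lower for ndhO against WT, 3 and 3 for pgr5 against WT, and 9 and 3 for pgr5 against ndhO, and the cause was not tested. Replicate numbers did not pair the libraries (same-number correlations -0.38 to 0.06, 0 of 9 over 0.1, 0 libraries closest to their own number), and the replicate block gave 0 genes and 1 list per contrast and changed no call. The 1 list per contrast became 0 in each with an estimated correlation, and without each library in turn ran from 0 to 5 for ndhO against WT, 1 to 6 for pgr5 against WT and 1 to 5 for pgr5 against ndhO, and 0 in each with both changes. For ribosomal proteins in pgr5 against ndhO, leaving out pgr5 3 turned the direction (adjusted p = 5.05e-04, or 0.990 with an estimated correlation) and leaving out ndhO 1 ended the call (adjusted p = 0.215), over a range of settings from 6.17e-13 to 0.994, and pgr5 3 had the highest level of the list (0.94). Of 1344 list tests under other settings, 28 newly passed, 24 no longer passed and 2 turned. Of 2548 fits of named genes, 119 changed sign with no call on either side and are counted as the same. Enrichment of annotation terms was not run. In the simulation, with 3 replicates and the dispersions fitted under the labels, most 2-fold changes were below detection.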

Other observations

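The tests on genes at 0 in 1 library were chosen before their results were seen, except that of the other libraries of the same label, which like the counts over sets of 3 libraries present or absent together came afterwards. The genes named next were also chosen after their values were seen, and none passed edgeR's test over all genes. TIP2-2, a probable aquaporin of the vacuole (LOC117853268), stood at 107 ± 8.53 CPM in the libraries labelled pgr5 and 181 ± 16.2 CPM in those labelled WT (SD, n = 3), a log2 difference of -0.75 with a standard error of 0.17. FKBP16-1, a chloroplast isomerase (LOC117854957), stood at 5.26 ± 1.26 CPM for pgr5 and 11.7 ± 0.443 CPM for ndhO (SD, n = 3). Cellulose synthase-like protein H1 (LOC117865243) stood at 3.81 ± 0.758 CPM for pgr5 and 20.9 ± 13.6 CPM for ndhO (SD, n = 3). DESeq2 called all 3 in those contrasts.

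Of the 23 genes called by DESeq2 in any contrast, 7 had counts in all 9 libraries, 11 were at 0 in libraries of a label and present in others of it, and 5, chosen here after their values were seen, followed the labels between which DESeq2 had tested. LOC117833632, LOC117838050, LOC117855042 and LOC117858443 were at 0 in all libraries labelled WT and present in the other 6, and LOC117850459 was at 0 in all labelled ndhO only. Also chosen after its values were seen, LOC117846273, an uncharacterized gene, had 464, 479 and 483 counts in the libraries labelled WT 2, WT 3 and ndhO 1 and 0 in the other 6. LOC117838735, LOC117850811, LOC117862125, LOC117834788 and LOC117839809, chosen in the same way, had counts only in WT 1, pgr5 2 and pgr5 3. All of these were among the 11, and the rest of the 11 followed neither the labels nor these sets of libraries. Over all 84 sets of 3 libraries, 23 genes had at least 10 counts in each of WT 1, pgr5 2 and pgr5 3 and 0 elsewhere, 6 did so in WT 2, WT 3 and ndhO 1, and at most 3 in any other set. Conversely, 16 genes were at 0 in ndhO 2, ndhO 3 and pgr5 1 with at least 10 counts in each of the other 6, against at most 6 for any other set. For the labels WT, ndhO and pgr5 the counts by the same limits were 0, 0 and 0 for genes present only there and 2, 0 and 0 for genes at 0 only there. The 3 sets named are those that labels moved by 1 column make, which gave 62 genes with any difference, so they may share a source with the edited genes, a hypothesis from the data it was found in.

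A further 304 genes had 0 counts in 1 library and at least 10 in each of the other 8, from 6 genes in the library labelled pgr5 1 to 95 in WT 3. These libraries had the highest and lowest totals, 18837265 and 11606570 counts. The next lowest totals, in pgr5 2 and WT 2, went with 60 and 42 such genes. The order was not strict. ndhO 1 held 21, fewer than ndhO 3 (29) and pgr5 3 (25), and WT 1 held 15 against 11 in ndhO 2, despite higher totals in ndhO 3, pgr5 3 and WT 1. A link with depth beyond Poisson counting was not tested. Counting error at low abundance is argued against, as Poisson counting at each gene's mean gives 0.0115 such genes. A neighbouring tested gene was raised by over 1 log2 unit for 8.56% of 292 genes and for 9.32% of genes matched on abundance. This argues against reads moved to such a neighbour in numbers that raise it that far. Reads moved to a much more abundant neighbour, or to a gene outside those tested, would not show. No test of the labelled genotype decided, since the selection for at least 10 counts in the other 8 libraries kept the other 2 of the same label above 0, so that their median log2 difference of 0.0699 from the 6 of the other labels could not have fallen below -1.47. A count over other genes, 2 at 0 in all 3 libraries of a labelled genotype, is too small to decide, differences between single plants were not tested, and the authors' deposited table called 40 of the 304 genes for pgr5.

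Other splits of the libraries were counted for each comparison. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real counts were 0, which no split can fall below (10 of 10 reached it), and the highest other counts were 4 for ndhO and WT, 14 for pgr5 and WT and 22 for pgr5 and ndhO. For all 9 libraries the real count was also 0, so that all 100 of 100 drawn splits reached it and the comparison says nothing about chance. The highest other count, 62 genes, was that of the labels moved by 1 column. The next, 51 and 40 genes, came from splits with WT 3, ndhO 1 and pgr5 2 as 1 set. These were the 3 libraries lowest in the NDH, photosystem I, antenna and Calvin-Benson lists. The split with the most genes at an unadjusted p under 0.05 also held that set. The structure of the libraries was not tested further. At an unadjusted p under 0.05 the real split had 343 genes, and the others a median of 651 and up to 2564, with 81 of them above the real one. Uniform p-values would give 898.5, above the median of the other splits.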
